A study of Homo sapiens with 6 samples.

How the data were processed

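A549 cells were profiled on 6 Affymetrix arrays in 3 groups of 2: cells given a PIAS3 plasmid, cells given a STAT3 siRNA, and EGF-stimulated control cells. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, cells were seeded for 12 h in 10% FBS, and RNA was taken 48 h after transfection. The authors deposited log2 values per probe set, and the submitters' processing notes name RMA with no version. RMA corrects background, normalizes across arrays and summarises probes, which compresses small changes of dim probe sets and assumes that most genes do not differ. The software, array annotation version and genome build are not given in the sources used here, and no scanner output was used. The sorted values of the arrays differed slightly from each other, with medians of 6.63 to 6.72 on the log2 scale.

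The table held 22277 probe sets in 6 array columns, all of them used. The 62 array control probe sets were left out, and 22215 were tested. Gene names came from the platform annotation supplied with the data: 19064 probe sets had 1 symbol, 1043 several and 2108 none. Of those with 1 symbol, 19052 were matched by gene identifier and 0 symbols needed updating. Probe sets with several symbols or none stayed unnamed. The probe set with the highest mean over the 6 arrays stood for each of 11963 genes.

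Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on the deposited log2 values. All 6 arrays entered one fit, with 1 mean per group. It had 3 residual degrees of freedom and 4.27 prior degrees of freedom. Adjusted p-values are Benjamini-Hochberg over all 22215 probe sets in each of 3 comparisons, with a threshold of 0.05. Errors beside log2 differences are the fit's standard errors. A total of 30 gene lists was fixed before the data were examined, together with the tests, the alternatives and the rule for named genes. The lists were tested with camera at a preset correlation of 0.01, on 1 probe set per gene, adjusted over the lists. They were tested again with an estimated correlation, where camera also uses only the fit's 3 residual degrees of freedom. A call lost there need not come from correlation between genes. The lists cover apoptosis, p53, STAT3, JAK and STAT, SUMO, EGF and ERK, interferon, NF-kB, stress, cell cycle, metabolism, adhesion and markers of other cell types. A gene is counted as adjusted over the list alone where Benjamini-Hochberg was applied to the list's members only.

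The rule for named genes was, per comparison, STAT3 and PIAS3, then up to 12 genes in each direction with an adjusted p under 0.05 and both arrays of one group beyond both of the other. Where none passed, the 5 with the smallest p in each direction were named. Up to 4 members of each described list with the smallest p were added, and up to 10 genes called in both comparisons against control. Of the genes that the rule names for PIAS3 against control, 1 with a higher level is not described in the text. Other members that passed over their list alone, and MX1, TNFSF10 and the genes named only in the closing part, were chosen after their values were seen.

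Chance values of the overlap between comparisons that share controls came from 100 simulations of unchanged groups. The fit was tested on simulated data in 20 runs with 200 changed probe sets, for the comparison of PIAS3 with control on 22215 probe sets. It recovered 77.7% of changes of 1 log2 and 98.6% of changes of 2 log2, and 5.17% of its calls were unchanged probe sets. Camera called 100% of simulated lists shifted by 0.5 log2. These simulations drew independent arrays of equal quality, which the real arrays need not be, and genes that vary independently of each other. In the real lists the estimated correlation was 0.88 for interferon, 0.79 for G1/S and 0.47 for G2/M genes, and 0.009 for TGF-beta genes. The simulations therefore cannot show how often camera at the preset 0.01 calls an unchanged list of correlated genes.

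Alternatives were a replicate block, quantile normalization again, centring on array medians, cyclic loess, a filter at the 40th percentile of mean level, eBayes with a trend or made robust, a fit of the 2 groups alone, an adjusted p of 0.10, fry, the mean of a gene's probe sets, and leaving out each array. Array weights were added after the data were seen. Where 1 array was left out, the remaining array of its group was assumed to vary like the other groups. Array pairs differed with an SD of 0.15 (control), 0.25 (STAT3 siRNA) and 0.35 (PIAS3) on the log2 scale, and no pair held identical columns. Array hybridization dates were not used here, so array batches were not tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.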

Results

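Gene expression was measured in A549 cells, an established human lung adenocarcinoma line, on 6 Affymetrix arrays in 3 groups of 2. One group received a plasmid encoding human PIAS3, a SUMO ligase known as an inhibitor of STAT3. Another received an siRNA against STAT3, the transcription factor itself. The third group was stimulated with EGF and, per its labels, not transfected. The series' design text places all groups in serum-free medium and then EGF, while the sample titles name EGF for the control arrays alone. RNA was taken 48 h after transfection, and no separate time is given for the control. Each array gave log2 values for 22215 probe sets that were not array controls, with medians between 6.63 and 6.72. The labels do not say that the 2 arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical, and their number limits the precision.

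The targeted genes were examined first. STAT3 (Entrez gene 6774, the brighter of its probe sets) stood at 10.23 and 9.94 in the STAT3 siRNA arrays, 10.18 and 9.70 in the PIAS3 arrays, and 10.50 and 10.43 in the control arrays. Its log2 difference from control was -0.38 ± 0.18 (SE, n = 2 per group) with the siRNA and -0.53 ± 0.18 with PIAS3, and neither passed the threshold (limma adjusted p of 0.9998 and 0.254). Its other probe set gave -0.33 ± 0.15 and -0.60 ± 0.15, and neither passed. The STAT3 level was therefore lower in all 4 transfected arrays than in both controls, by amounts that the test did not separate from the spread. PIAS3 (Entrez gene 10401, with a single probe set) differed from control by 0.04 ± 0.11 in the arrays labelled PIAS3 and by -0.13 ± 0.11 in the siRNA arrays. The position of its probes relative to the plasmid's insert is not given in the sources used here, so a level near that of the control checks nothing about the plasmid.

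The comparison of PIAS3 with control asks which genes, those of apoptosis first, differed in cells given the PIAS3 plasmid. TFF1, a secreted trefoil peptide of mucous epithelia, fell most among the genes past the threshold, by 3.11 ± 0.21 on the log2 scale (8.66-fold, adjusted p = 0.0202). TMEM158, a membrane protein induced by Ras signalling, fell by 1.98 ± 0.16 (adjusted p = 0.0361). The chemokine CCL2 fell by 1.67 ± 0.17, the sialomucin PODXL by 1.58 ± 0.18, the ADP-ribosyltransferase TIPARP by 1.57 ± 0.18 and the matricellular protein CCN2 by 1.13 ± 0.12, each at an adjusted p of 0.0484. Higher levels were found for the potassium channel subunit KCNJ16 (1.43 ± 0.16), the mitochondrial acyl-CoA synthetase ACSM3 (1.19 ± 0.12) and the insulin-like peptide INSL4 (1.12 ± 0.13), at the same adjusted p.

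CRISPLD2, NAV3 and SAMD4A also fell, by 1.25 ± 0.13, 1.13 ± 0.11 and 1.08 ± 0.13, for NAV3 and SAMD4A by their brightest probe sets alone. The other NAV3 probe sets gave 0.03 ± 0.10 and -0.14 ± 0.14 and the other SAMD4A probe sets -0.23 ± 0.11, -0.25 ± 0.13 and -0.16 ± 0.13, and none of these passed. The other NAV3 probe sets read no higher than the control probe sets for an absent transcript (3.26 to 3.93) in any array, so they decide nothing. PRSS3 and PRSS2 were lower by 1.32 and 0.99 in the fit, but these trypsinogen genes are near-identical and their probe sets can hardly tell them apart, so which of them changed is uncertain. In all, 6 probe sets were higher and 16 lower, and 3 of these 22 had no single gene symbol. At an unadjusted p under 0.05 the counts were 1334 and 1747. Both arrays of one group lay beyond both arrays of the other for 45.4% of probe sets, where chance gives 33.3%. The calls depended on processing and on single arrays: 0 higher and 2 lower were called with quantile normalization again or with the filter on dim probe sets, and 10 and 29 with cyclic loess. With arrays left out, the calls were lost without control replicate 1 or without control replicate 2. The TFF1 difference stayed at -3.09 and -3.14 in these fits, which have fewer residual degrees of freedom. Few calls were left without PIAS3 replicate 1. The counts were 130 and 132 in a fit of the 2 groups alone, since the siRNA arrays are not in this comparison but enter its spread. Without PIAS3 replicate 2 the fit rests on PIAS3 replicate 1 alone, which had raised interferon-stimulated genes and poly-A spike-ins. The larger counts of that fit describe that array and not the PIAS3 group. The actin probe sets at the 3' end read above those at the 5' end by 0.43 and 0.28 in the PIAS3 arrays, against 0.12 and 0.10 in the controls and 0.16 and 0.23 in the siRNA arrays. For GAPDH the difference was 0.40 and 0.37 in the PIAS3 arrays, against 0.36 and 0.29 in the controls and 0.29 and 0.40 in the siRNA arrays.

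**Figure D1:**
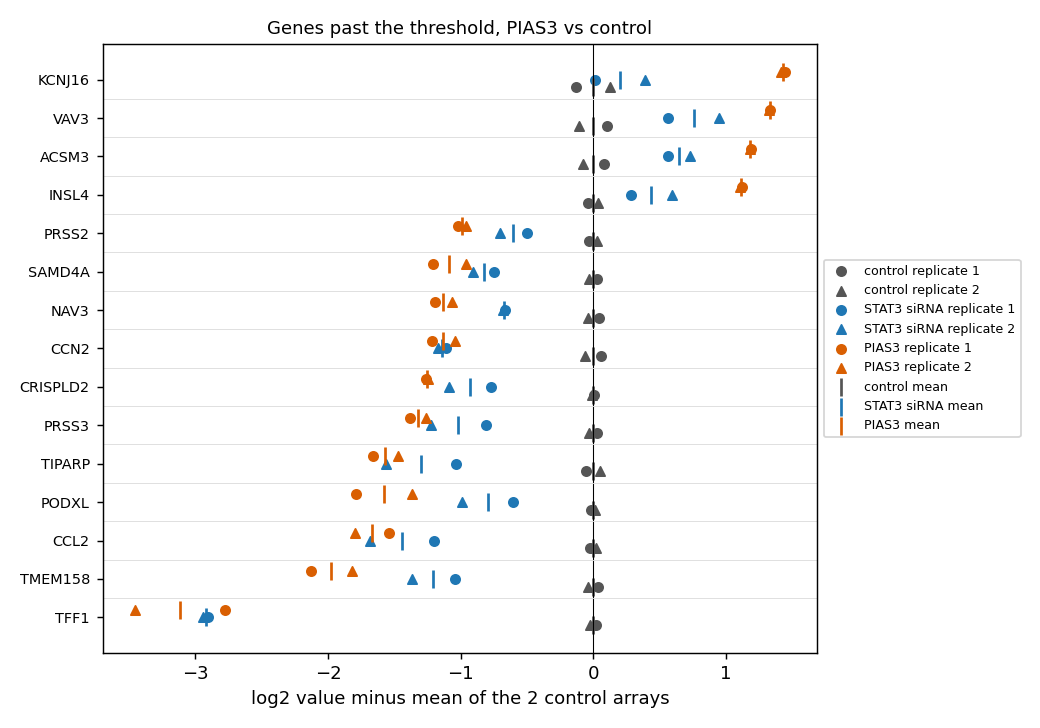
Each row is a gene past the threshold in the comparison of PIAS3 with control. The horizontal axis is the log2 value minus the control mean, with points for single arrays (circles replicate 1, triangles replicate 2) and ticks for group means, and TFF1 lies lowest, at -3.11 in the PIAS3 mean and -2.92 in the STAT3 siRNA mean.

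Genes of apoptosis, the subject named in the series' design text, showed no member past the threshold in this comparison. The 13 measured pro-apoptotic BCL2 family genes had a median log2 difference of -0.09, the 18 anti-apoptotic genes -0.04, the 16 caspase and apoptosome genes -0.03 and the 19 death receptor genes -0.05. Adjusted over the list alone, 0 members of each of these 4 lists passed, and 0 passed over all genes. CASP8, the initiator caspase of death receptors, stood 0.58 ± 0.18 above control with an adjusted p of 0.149 over its list. BAX, a pore-forming pro-apoptotic protein, stood at -0.34 ± 0.15 (adjusted p = 0.201 over its list). Of 29 p53 target genes, GADD45A and PLK2 were lower, by -0.77 ± 0.14 and -0.52 ± 0.11, when adjusted over the list alone, and 0 passed over all genes. The p53 target list had a median of -0.01 and an adjusted p of 0.837 in camera, a test of whether a list's genes shift against all others. The other 4 lists did not pass either, at adjusted p-values of 0.419, 0.566, 0.826 and 0.762. The medians of the caspase, death receptor and p53 lists were negative while their means were positive, and camera pointed down for death receptor genes and up for the others.

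Adhesion, matrix and transcription factor genes of the TGF-beta and mesenchymal list moved in both directions. Of 27 measured, 12 were lower and 4 higher adjusted over the list alone, and 1 (CCN2) passed over all genes. CCN1 and CCN2, matricellular proteins, and COL4A1, a basement membrane collagen, were lower by -1.29 ± 0.20, -1.13 ± 0.12 and -1.14 ± 0.18. ID1, an inhibitor of basic helix-loop-helix factors, was higher by 1.69 ± 0.33. The list's median was -0.17 (camera adjusted p = 0.0296, and adjusted p = 0.771 with an estimated correlation). That call was lost without PIAS3 replicate 2 (adjusted p = 0.444) and without control replicate 1 (0.0533).

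Antioxidant genes controlled by NRF2 shifted up as a group in camera (adjusted p = 5.59e-10, and adjusted p = 0.792 with an estimated correlation). All 24 measured lay above control, with a median of 0.34, and 9 passed adjusted over the list alone, while 0 passed over all genes. These included the glutathione peroxidase GPX2 (1.82 ± 0.35), the heme oxygenase HMOX1 (1.42 ± 0.31) and GCLC (0.93 ± 0.21), the catalytic subunit of the enzyme that starts glutathione synthesis.

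The STAT3 target list shifted upward (median 0.07, camera adjusted p = 0.0296, and adjusted p = 0.792 with an estimated correlation). Adjusted over the list alone, 7 of 33 members were higher and 0 lower, and 0 passed over all genes. The fibrinogen chains FGG, FGA and FGB, secreted acute phase proteins, were higher by 3.31 ± 0.53, 2.89 ± 0.46 and 2.73 ± 0.62, and the transcription factors BCL6 and CEBPB by 1.38 ± 0.29 and 0.88 ± 0.17. FGG and FGB also read high in siRNA replicate 2 (7.92 and 7.63) but less so in siRNA replicate 1 (6.21 and 5.47). The controls read 5.93 and 5.64 for FGG and 5.73 and 5.59 for FGB, so this rise was not particular to the PIAS3 arrays. The call was lost without PIAS3 replicate 1 (adjusted p = 0.525), without STAT3 siRNA replicate 1 (0.0542) and with the mean of a gene's probe sets (0.0986). Among 25 other JAK, STAT and PIAS components, STAT4 was higher (0.61 ± 0.12) and EGFR lower (-0.61 ± 0.12) adjusted over the list alone, 0 passed over all genes, and the list did not pass (camera adjusted p = 0.657).

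Interferon-stimulated genes differed between the 2 PIAS3 arrays. Their median over 40 genes was 2.79 above the control mean in PIAS3 replicate 1 and -0.00 in replicate 2. MX1, an antiviral GTPase, read 10.61 and 4.86 in these arrays. The list passed in camera (median 1.42, adjusted p = 6.80e-09, and adjusted p = 0.792 with an estimated correlation), with 0 members passing either over the list alone or over all genes. Without PIAS3 replicate 1 its direction turned and the call ended (adjusted p = 0.564). Poly-A spike-in probe sets in PIAS3 replicate 1 had medians of 1.44 and 1.38 above the control mean in their 2 series.

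Genes of G1/S and DNA replication shifted down (median -0.32, camera adjusted p = 2.87e-08, and adjusted p = 0.792 with an estimated correlation), with a median of -0.60 in PIAS3 replicate 1 and -0.07 in replicate 2. Of 40 genes, 0 passed over the list alone or over all genes, and CCNE2, a cyclin of S phase entry, stood at -1.21 ± 0.34. G2/M and mitosis genes shifted up (median 0.16 over 38, adjusted p = 0.000869, and adjusted p = 0.792 with an estimated correlation), with 0 passing over the list alone or over all genes and the call lost without PIAS3 replicate 2 (adjusted p = 0.615). Histone genes shifted up (median 0.23 over 11, adjusted p = 0.0277, and adjusted p = 0.771 with an estimated correlation). Of these, H2AC6 (0.85 ± 0.17), H2BC21 (0.83 ± 0.17), H2BC5 and H2BC12 were higher adjusted over the list alone and 0 over all genes, and the call was lost without PIAS3 replicate 2 (adjusted p = 0.333). Autophagy and lysosome genes shifted up (median 0.12 over 25, adjusted p = 0.0296, and adjusted p = 0.771 with an estimated correlation), with the kinase ULK1 (0.79 ± 0.14) and the phosphoinositide-binding WIPI1 (0.68 ± 0.13) higher adjusted over the list alone, 0 over all genes, and the call lost without PIAS3 replicate 2 (adjusted p = 0.333) and without control replicate 1 (0.0522).

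Cholesterol synthesis genes shifted down (median -0.16 over 17, adjusted p = 0.0296, and adjusted p = 0.792 with an estimated correlation), with 0 members passing over the list alone or over all genes, among them HMGCS1 at -0.39 ± 0.12. That call was lost without PIAS3 replicate 1 (adjusted p = 0.607), without STAT3 siRNA replicate 1 (0.0592), without control replicate 1 (0.0581), with cyclic loess (0.0698) and with the filter on dim probe sets (0.102). In all, 9 of 30 lists passed in camera and 0 with an estimated correlation, a setting that also has only 3 degrees of freedom. The estimates for the autophagy (0.006), TGF-beta (0.009) and histone (-0.07) lists lay below the preset 0.01. Their calls were therefore not lost to a higher correlation.

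The other lists did not pass in camera. Adjusted over the list alone, 6 EGF and ERK response genes passed, with HBEGF (-0.92 ± 0.14), EGR3 and 3 more lower and SPRY1 higher, and 0 over all genes (list adjusted p = 0.152, which fell to 6.45e-08 without PIAS3 replicate 1). EGR3 read 3.72 and 3.49 against 4.50 and 4.48 in the controls, and the lower values lie within the range of the absent-transcript probe sets (3.26 to 3.93), so its difference is only a lower bound in size. Epithelial genes moved both ways, CDH1 higher (1.09 ± 0.16) with ELF3, and CLDN1 (-1.14 ± 0.18), CEACAM6, KRT19 and OCLN lower over the list alone, 0 over all genes (adjusted p = 0.218). In the ATF4 and CHOP list, CTH, CEBPB, DDIT4 and CHMP1B were higher and STC2 lower over the list alone, 0 over all genes (adjusted p = 0.139, and 0.000990 without PIAS3 replicate 1). Only CCL2 passed among 23 NF-kB targets, over the list alone and over all genes (list adjusted p = 0.655, and 0.000990 without PIAS3 replicate 1).

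CCND3 was higher and CDK4 lower among CDK inhibitors and cyclin D genes, PFKFB3 higher and P4HA2 lower among hypoxia and glycolysis genes, and CRYAB higher and HSPB8 lower among heat shock genes, each over the list alone with 0 over all genes. The camera adjusted p-values of these 3 lists were 0.918, 0.826 and 0.387. ER chaperone (0.655), SUMO pathway (0.987), ribosomal protein (0.826), mitochondrial respiratory chain (0.387) and proteasome (0.0598) lists had 0 members past either threshold. The respiratory chain list passed without PIAS3 replicate 1 (4.98e-05), with quantile normalization (0.0457) and with cyclic loess (0.0196). The proteasome list passed without PIAS3 replicate 2 (0.000304) and with the mean of a gene's probe sets (0.0231). Markers of other cell types showed CD14 higher (0.84 ± 0.13) among 17 leukocyte markers and SPARC lower (-3.29 ± 0.77) among 14 fibroblast markers over the list alone, 0 over all genes, and 0 of 11 endothelial markers. Their lists' adjusted p-values were 0.671, 0.762 and 0.916. Median and mean differed in sign for the SUMO, NF-kB, hypoxia and cyclin D lists; camera followed the mean for the SUMO and cyclin D lists and the median for the others.

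**Figure D2:**
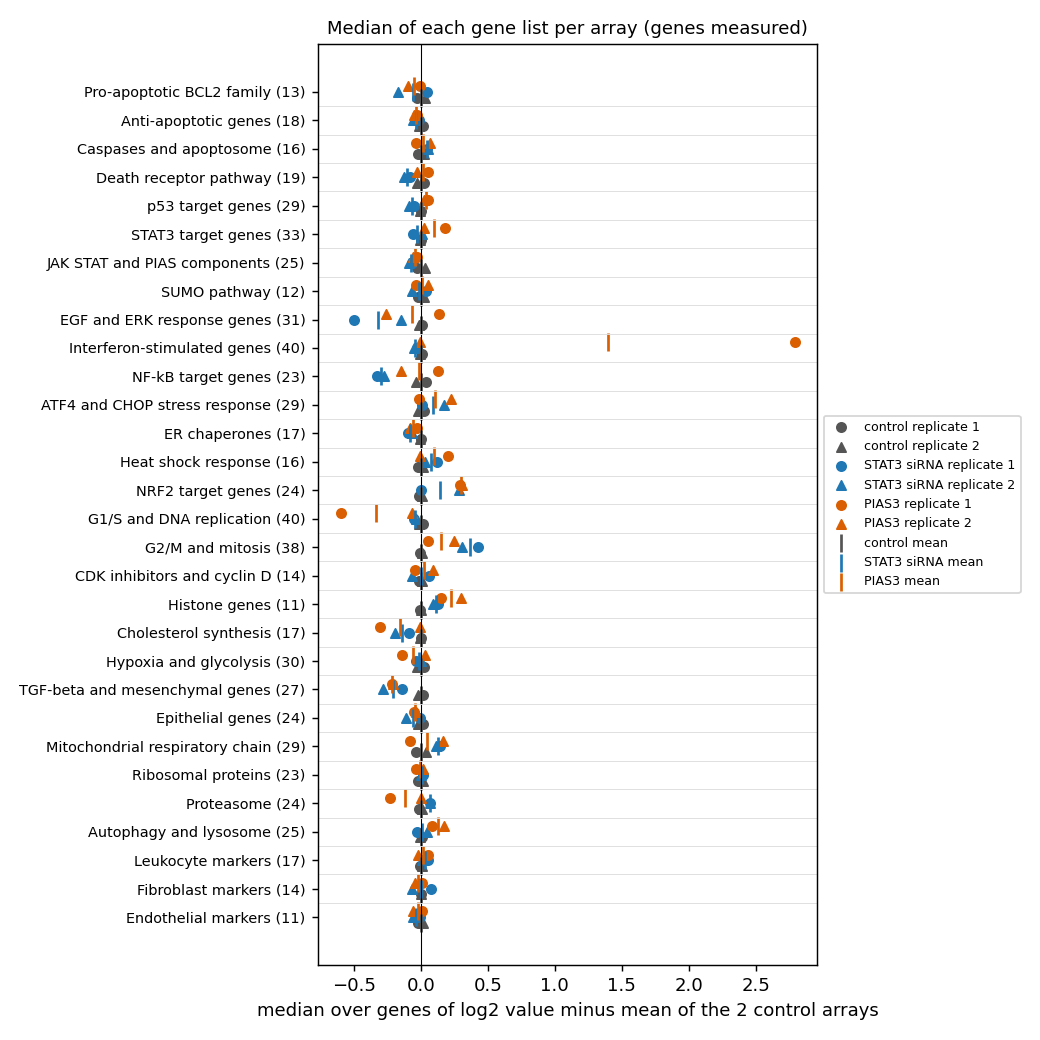
Each row is a gene list fixed before the values were seen, with the number of genes measured. The horizontal axis is the list's median log2 value minus the control mean, with points for single arrays (circles replicate 1, triangles replicate 2) and ticks for the mean of both arrays' medians, and the interferon list lies at 2.79 in PIAS3 replicate 1, while PIAS3 replicate 2 stands at -0.00.

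The comparison of the STAT3 siRNA with control asks which genes differed in cells given the siRNA. TFF1 fell by 2.92 ± 0.21 on the log2 scale (7.58-fold, adjusted p = 0.0316), from 10.08 and 10.04 in the controls to 7.16 and 7.12. The siRNA arrays stood apart: replicate 2 differed less from PIAS3 replicate 2 (SD of the difference over probe sets 0.19) than from siRNA replicate 1 (0.25), which lay nearest to control replicate 2 (0.20). All 38 mitotic genes lay above control, with 0 past the threshold over the list alone, and camera called the group higher. It called EGF and ERK response genes and NF-kB targets lower, and each of these 3 calls was lost with an estimated correlation (adjusted p = 0.555 with an estimated correlation).

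TFF1 was the only probe set past the threshold, 0 being higher and 1 lower in limma, against 461 and 616 at an unadjusted p under 0.05. Its call was lost without either siRNA array (adjusted p = 0.0685 without replicate 1 and 0.539 without replicate 2) and without either control array (1.0 and 0.940), while its log2 difference stayed at -2.94, -2.90, -2.90 and -2.94 in these fits, which have fewer residual degrees of freedom. It was also lost with quantile normalization again (-2.90, adjusted p = 0.0609) and cyclic loess (-2.92, adjusted p = 0.0707). Without siRNA replicate 1, 2 higher and 3 lower probe sets were called, and without either PIAS3 array 0 higher and 3 lower. Both arrays of one group lay beyond both of the other for 37.5% of probe sets, where chance gives 33.3%.

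G2/M and mitosis genes had a median of 0.36 (camera adjusted p = 1.73e-23, and adjusted p = 0.555 with an estimated correlation). Adjusted over the list alone 0 of 38 passed, and 0 over all genes, while 23 had an unadjusted p under 0.05. The proliferation marker MKI67 stood at 0.54 ± 0.13, the mitotic kinesin KIF20A at 0.59 ± 0.15 and the kinetochore motor CENPE at 0.58 ± 0.14.

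EGF and ERK response genes had a median of -0.34 (camera adjusted p = 3.26e-09, and adjusted p = 0.555 with an estimated correlation). Adjusted over the list alone 5 of 31 were lower and 0 higher, and 0 passed over all genes. These were the stress-induced factor ATF3 (-2.50 ± 0.47), the EGF receptor ligand HBEGF (-1.07 ± 0.14), the immediate early factor EGR3, JUN and the feedback inhibitor SPRY2. EGR3 read 3.53 and 3.40 with the siRNA, again within the range of the absent-transcript probe sets, so its difference is a bound here too. Among NF-kB targets (median -0.22, camera adjusted p = 3.38e-06, and adjusted p = 0.555 with an estimated correlation), CCL2 (-1.44 ± 0.17) and RELB (-0.55 ± 0.11) were lower over the list alone, and 0 over all genes.

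In the TGF-beta and mesenchymal list, 6 of 27 were lower and 2 higher over the list alone, and 0 over all genes (median -0.20, camera adjusted p = 2.15e-05, and adjusted p = 0.542 with an estimated correlation). CCN2 was lower by -1.14 ± 0.12, COL4A1 by -0.97 ± 0.18 and CCN1 by -1.01 ± 0.20, and ID2 and ID1 were higher by 1.36 ± 0.33 and 1.05 ± 0.33. Of 24 epithelial genes, the adhesion molecule CEACAM6 (-1.47 ± 0.18) and the tight junction protein CLDN1 (-0.98 ± 0.18) were lower over the list alone and 0 over all genes. That list shifted down in camera (adjusted p = 0.0108, and adjusted p = 0.555 with an estimated correlation), a call lost without siRNA replicate 2 (adjusted p = 0.189).

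Respiratory chain genes shifted up (median 0.12, adjusted p = 4.75e-05, and adjusted p = 0.688 with an estimated correlation), as did NRF2 targets (median 0.15, adjusted p = 8.09e-05, and adjusted p = 0.688 with an estimated correlation). The NRF2 median was 0.00 in siRNA replicate 1 and 0.28 in replicate 2, and the call was lost without replicate 2 (adjusted p = 0.984). Cholesterol synthesis genes shifted down (median -0.11, adjusted p = 0.00391, and adjusted p = 0.627 with an estimated correlation). Death receptor genes shifted down (median -0.14, adjusted p = 0.0210, and adjusted p = 0.555 with an estimated correlation), a call lost without siRNA replicate 1 (adjusted p = 0.340), without control replicate 1 (0.0920) and with the filter on dim probe sets (0.0510). Proteasome genes shifted up (median 0.07, adjusted p = 0.0476, and adjusted p = 0.865 with an estimated correlation), a call lost without either siRNA array (adjusted p of 0.102 and 0.244) and without either control array (0.0946 and 0.0827). The proteasome call was also lost with quantile normalization (adjusted p = 0.0759), cyclic loess (0.0682), the filter (0.0651) and the mean of a gene's probe sets (0.122). In these 5 lists 0 members passed over the list alone or over all genes.

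The remaining apoptosis lists did not pass, with medians of -0.04 for pro-apoptotic BCL2 genes, -0.02 for anti-apoptotic genes and 0.08 for caspases and apoptosome, and 0 members past either threshold. MCL1, an anti-apoptotic BCL2 relative, stood at -0.46 ± 0.19 (adjusted p = 0.869 over its list). Among p53 targets GADD45A was lower (-1.0004 ± 0.14) over the list alone, 0 over all genes (list adjusted p = 0.194). The STAT3 target list had a median of -0.04, 0 of 33 members past either threshold and a camera adjusted p of 0.821. ATF3 and STC2 were lower over the ATF4 and CHOP list alone, 0 over all genes. The list itself pointed up, with a median of 0.13, 22 members higher and 7 lower. It did not pass (camera adjusted p = 0.162), but passed upward with the 2 groups alone (0.0319) and with some single arrays left out. Interferon-stimulated genes had a median of -0.03 and a camera adjusted p of 0.912. The other 13 lists had 0 members past either threshold and did not pass, though the ER chaperone list passed downward without siRNA replicate 2 (0.0148) and the JAK, STAT and PIAS list, also downward, without control replicate 1 (0.0403). Median and mean differed in sign for the STAT3 target, cyclin D and fibroblast lists; camera pointed down, up and down. In all, 10 of 30 lists passed in camera and 0 with an estimated correlation. For the death receptor (-0.02) and TGF-beta (0.009) lists the estimate lay below the preset 0.01, so their calls were not lost to a higher correlation.

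The direct comparison of PIAS3 with the STAT3 siRNA asks where the transfections differed from each other. No probe set passed the threshold, and the genes with the smallest p are given as values. KCNJ16 stood 1.23 ± 0.16 higher in the PIAS3 arrays, TMEM47 0.92 ± 0.14, WIPI1 0.78 ± 0.13, CD14 0.74 ± 0.13 and C14orf132 0.71 ± 0.11. The neuropeptide GAL stood at -1.05 ± 0.18, DCBLD2 at -0.99 ± 0.18, TMEM158 at -0.77 ± 0.16, the membrane and actin linker MSN at -0.67 ± 0.11 and GATAD2A at -0.56 ± 0.11. The adjusted p was 0.607 for each of these 10. The other probe sets of GAL and TMEM47 gave -0.06 ± 0.14 and 0.13 ± 0.11, the TMEM47 one at the level of the absent-transcript probe sets in all arrays. With limma 0 probe sets were higher and 0 lower, against 793 and 1006 at an unadjusted p under 0.05. Without PIAS3 replicate 2 the group is replicate 1 alone, the array with raised interferon-stimulated genes and poly-A spike-ins. Calls in that fit describe that array and not the PIAS3 group. Without siRNA replicate 2, 1 lower was called. Both arrays of one group lay beyond both of the other for 34.96% of probe sets, where chance gives 33.3%.

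Interferon-stimulated genes were higher in the PIAS3 group (median 1.45, camera adjusted p = 3.89e-12, and adjusted p = 0.755 with an estimated correlation), with 0 of 40 past either threshold. That direction turned without PIAS3 replicate 1 (adjusted p = 0.781). G1/S genes (median -0.26, adjusted p = 3.71e-10), G2/M genes (-0.19, 2.29e-06) and proteasome genes (-0.18, 1.36e-05) were lower, and NRF2 targets (0.20, 3.66e-06), STAT3 targets (0.12, 0.000305), NF-kB targets (0.19, 0.000790), EGF and ERK response genes (0.21, 0.000809) and autophagy genes (0.06, 0.0137) higher in camera. Each of these calls was lost with an estimated correlation (adjusted p = 0.755, and 0.914 for EGF and ERK response genes). Without PIAS3 replicate 1 the G1/S (adjusted p = 0.155), G2/M (0.257), proteasome (0.246), STAT3 target (0.257), NF-kB (0.686) and EGF and ERK (0.691, direction turned) calls ended. The NRF2 (0.476), EGF and ERK (0.369) and autophagy (0.311) calls ended without siRNA replicate 1, and the autophagy call without PIAS3 replicate 2 (0.319). The ATF4 and CHOP list, not past the threshold with all arrays (0.393), passed without PIAS3 replicate 1 (0.0139) and without siRNA replicate 2 (0.00532), and the respiratory chain list (0.0758) passed without PIAS3 replicate 2 (0.000201).

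Over single lists alone, the autophagy genes WIPI1 (0.78 ± 0.13) and GABARAPL1 (0.95 ± 0.17), the adherens junction cadherin CDH1 (0.85 ± 0.16), CD14 (0.74 ± 0.13) and the histone genes H1-2 (0.44 ± 0.11), H2BC21 (0.60 ± 0.17), H2AC6 and H2BC5 were higher in the PIAS3 group, and 0 of them over all genes. The histone (adjusted p = 0.104, and 0.0326 with the filter on dim probe sets), epithelial (0.720) and leukocyte (0.927) lists did not pass. In all, 9 of 30 lists passed in camera. Signs of median, mean and test differed for the SUMO, heat shock, hypoxia and TGF-beta lists, which did not pass. Of the 4 apoptosis lists and the p53 targets 0 members passed either threshold. The TRAIL ligand gene TNFSF10 read 8.50 in PIAS3 replicate 1 and 4.34 in replicate 2, against 4.53 and 4.38 with the siRNA.

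Both transfections were set against the same controls to ask whether they changed the same genes. TFF1 was the 1 gene called in both, lower in each. Of the 15 genes called with PIAS3, 15 had the same sign with the siRNA, and 14 also an unadjusted p under 0.05 in limma. The median size with the siRNA was 0.61 of the PIAS3 difference. These genes were picked by the PIAS3 comparison, and the shared controls push both differences the same way. Which probe sets were called in both depended on single arrays, and TFF1 was not among those called without siRNA replicate 1. Across probe sets, which are not independent replicates, the log2 differences correlated at r = 0.63, where unchanged groups simulated against shared controls gave 0.50 (0.44 to 0.58). Their covariance was 0.0353 against 0.0167 simulated, and 0.00585 from the 2 control arrays' own spread. At an unadjusted p under 0.05 in both, 682 probe sets moved the same way and 3 opposite ways, against 283 and 7.62 simulated and 76.1 for the same way in independent lists. Over all probe sets, 66.8% had the same sign in both, against 66.6% simulated (65.9 to 67.5). The simulations gave all groups the same spread, while the control arrays differed less (SD 0.15) than the siRNA (0.25) and PIAS3 arrays (0.35). The simulated share therefore cannot decide whether 66.8% is an excess. Splitting the controls would leave 1 array a side, so the part of the shared controls was not measured directly. The simulations already shared controls, and their covariance (0.0167) was above that from the controls' own spread (0.00585). Part of the excess in correlation, covariance and counts may still come from the shared controls, if that spread understates how control cultures vary. The controls were, per their labels, not transfected, and no mock-transfected arrays are among the samples used here. Differences shared by both groups, TFF1 included, therefore cannot be told apart from effects of transfection itself. The sample titles also name EGF for the controls alone, unlike the design text, and no harvest time is given for the control. Effects of EGF exposure or of timing cannot be told apart from these shared differences either. The correlation was 0.32 without siRNA replicate 2 and 0.47 without PIAS3 replicate 2.

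**Figure D3:**
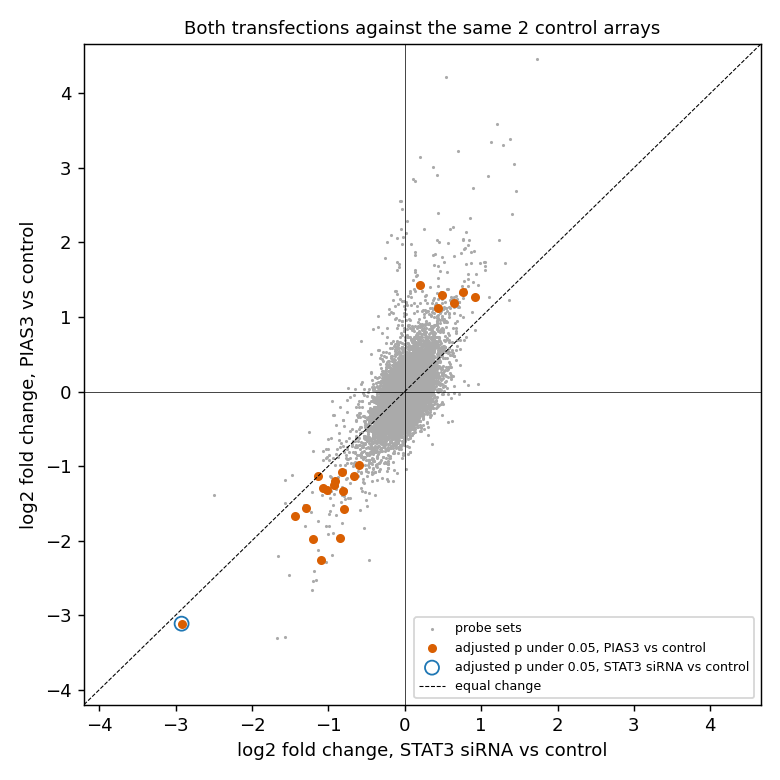
Each point is a probe set, with the log2 fold change of the STAT3 siRNA against control on the horizontal axis and of PIAS3 against control on the vertical axis. Filled points are the 22 probe sets past the threshold with PIAS3, the open circle marks the 1 past it with the siRNA, TFF1, and the dashed line marks equal change.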

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

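All tests of explanations in this part were chosen after the values were seen. A signal in probe sets outside the comparisons stood above the control arrays: the poly-A spike-in probe sets, which report RNA added before labelling and come in 2 series of 12, had medians of 1.44 and 1.38 above the control mean in PIAS3 replicate 1, against -0.13 in PIAS3 replicate 2 for each series. The hybridization spike-in probe sets, in 2 series of 9, had medians of 0.47 and 0.51 above it in the same array. The labels do not say how much spike-in was added. Actin probe sets at the 3' end read above those at the 5' end by 0.43 in that array and 0.28 in PIAS3 replicate 2, against 0.12 and 0.10 in the controls.

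In PIAS3 replicate 1, 35 of 40 interferon-stimulated genes stood over 1 log2 above the control mean, led by IFIT1 (12.36 against 4.18 and 4.32 in the controls), MX1, IFIH1 and IFI27. Lower RNA input, which the spike-ins and the actin values leave possible for this array, predicts no shift of one gene class: the highest median among 10000 random lists matched on level was 0.21, against 2.79. RNA from leukocytes is argued against by a leukocyte marker median of 0.0541, with the largest shift at 0.99. In replicate 2 the median was -0.0034 and 1 gene stood over 1 log2, so the shift was not shared by both PIAS3 arrays. That value restates the difference first seen and is no separate test. Open are an interferon response of that culture, for example to transfected plasmid DNA, and a wrong label or a swap with a sample outside the series, which were not tested.

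STAT3 siRNA replicate 2 lay with the PIAS3 arrays and replicate 1 with the controls over the 79 genes that differed by over 1 log2 between the siRNA arrays, 45 higher and 34 lower in replicate 2. Independent chance differences between the siRNA arrays predict that about as many of these genes lie on either side in other arrays, yet 93.7% lay on replicate 2's side in one PIAS3 array and 94.9% in the other. If a true siRNA array resembled replicate 1, a swap of replicate 2 with a PIAS3 array would leave a PIAS3 array near control. The PIAS3 medians were 1.25 and 1.498 towards replicate 2. If a true siRNA array resembled replicate 2, a swap of replicate 1 with a control array would part the controls. They lay 0.0182 apart in the median, while siRNA replicate 1 stood at -0.04. Which replicate shows the siRNA state is not known, so these values exclude neither swap. A control array labelled as siRNA replicate 1 is not decided: over the 173 genes called between PIAS3 and control in the fit of these 2 groups alone, replicate 1 had a median shift of 0.27 towards PIAS3 against 0.96 in replicate 2, while TFF1 at 7.16, against 10.08 and 10.04 in the controls, and the mitotic list at 0.43 go against it. Another wrong label, uneven delivery of the siRNA and a culture state shared by 3 arrays stay open and were not tested.

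EGF and ERK response genes were lower with the STAT3 siRNA, by -0.34 in the median, and the lowest of 10000 random lists matched on level lay at -0.14, which argues against chance spread of genes that vary each on its own. Random lists ignore that these genes vary together, so a second test was added after that result was seen. It leaves shared variation between cultures open: the PIAS3 arrays differed from each other by 0.40 in the list's median and the siRNA arrays by 0.35, while the control arrays differed by only 0.02. A response to the siRNA alone cannot be told apart from others, because PIAS3 replicate 2 stood at -0.26 and replicate 1 at 0.14. Transfection itself cannot be told apart either: the medians of the 4 transfected arrays ran from -0.49 to 0.14, and the series has no arrays of mock-transfected cells among the samples used here. The sample titles name EGF for the controls alone, unlike the design text, and no harvest time is given for the control. Whether EGF exposure or timing differed between the groups was not tested.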

How the results depend on the processing

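Array weights were chosen after the data were seen. STAT3 and PIAS3 stayed without a call under all alternatives run and kept their direction, except STAT3 between the transfections, which turned to 0.09 without PIAS3 replicate 2, and no scaling moved the median of all genes by over 0.1. The cause of each change was not tested, except that leaving out an array, or fitting 2 groups, changes the residual degrees of freedom. Signal over background limits dim probe sets, which the 40th percentile filter removed.

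Counts for PIAS3 against control are given as higher and lower probe sets (6 and 16), then those of at least 1 log2 (6 and 15). The replicate block gave 1 and 1, then 1 and 1; the numbers do not pair the arrays, whose deviations correlated at -0.05, -0.06 and 0.09, and it ended the TGF-beta and mesenchymal list call for PIAS3 (adjusted p = 0.0662), which left 8 lists in place of 9. Quantile normalization gave 0 and 2, then 0 and 2. Cyclic loess gave 10 and 29, then 7 and 24. The filter gave 0 and 2, then 0 and 2. Robust eBayes gave 15 and 25, then 13 and 23. The 2 groups alone gave 130 and 132, then 91 and 84. An adjusted p of 0.10 gave 115 and 139, then 54 and 65. Array weights gave 57 and 86, then 42 and 57. Leaving out each array gave 0 to 541 and 0 to 691, then 0 to 259 and 0 to 168. Of the 22 probe sets, 1 was shared with the 2 called without PIAS3 replicate 1.

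For the STAT3 siRNA, the 1 lower probe set, also at 1 log2, became 0 with quantile normalization or cyclic loess, 3 with the 2 groups alone and 8 with array weights, and leaving out each array gave 0 to 3, with 0 to 2 higher. For PIAS3 against the siRNA, it gave 0 to 282 higher and 0 to 262 lower, 0 to 184 and 0 to 45 at 1 log2, with 544 in all without PIAS3 replicate 2. The 1 shared call became 0 with quantile normalization or cyclic loess, 7 with array weights and 0 to 5 without an array. The correlation ran from 0.32 to 0.70 without an array.

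Lists past the threshold (9, 10 and 9) became 0, 0 and 0 with an estimated correlation and with fry, and leaving out an array gave 6 to 10, 8 to 11 and 3 to 10. Without PIAS3 replicate 1, 3 lists turned direction: interferon genes against control (adjusted p = 0.564, the others without an array down to 1.12e-51) and against the siRNA (0.781, down to 1.35e-57), and EGF and ERK genes against the siRNA (0.691, down to 2.49e-08).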

Other observations

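All genes in this part were chosen after their values were seen, as single genes with no test of a group. Among those that differed most between the siRNA arrays, CPS1, the first enzyme of the urea cycle, read 9.05 in siRNA replicate 2, 9.74 and 9.38 in the PIAS3 arrays, 6.80 in siRNA replicate 1, and 6.61 and 6.40 in the controls. TM4SF20 read 7.61 in siRNA replicate 2 and 4.68 in replicate 1, S100P 9.14 and 6.89, and the fibrinogen chain FGB 7.63 and 5.47. In the other direction SPARC, a matrix glycoprotein, read 7.05 in siRNA replicate 2 and 9.90 in replicate 1, PDGFC 4.94 and 7.32, and the actin-binding TAGLN 8.52 and 10.76. The controls read 9.95 and 10.14 for SPARC. The fixed fibroblast marker list had medians of 0.07 and -0.07 in siRNA replicates 1 and 2.

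Among single genes that were lower in PIAS3 replicate 1 than in replicate 2, PHGDH, the first enzyme of serine synthesis, stood 1.26 above the control mean in PIAS3 replicate 2 and 0.19 in replicate 1, PSAT1 0.41 and -1.19, and the asparagine synthetase ASNS 0.85 and -0.57. These are single arrays, with no test between them. In the siRNA arrays PHGDH read 9.55 and 9.62 against 8.82 and 8.74 in the controls. PSAT1 read 10.72 and 10.59 against 9.91 and 10.15, and ASNS 11.17 and 11.23 against 10.47 and 10.38. Higher levels than in the controls were therefore not particular to PIAS3 replicate 2. Of the 15 genes that most exceeded replicate 2 in replicate 1, 13 were in the interferon list, and the others were TRIM22 and TNFSF10. Leaving out the interferon list lowered the SD of the difference between the PIAS3 arrays from 0.37 to 0.31.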
